A study of Arabidopsis thaliana with 32 samples.

How the data were processed

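The 32 arrays covered 16 groups, shoots and roots at 8 times, with 2 arrays per group. The values used were the deposited MAS5 signal, made by the authors and scaled so that each array had a 2% trimmed mean near 100, as read from the submitters' processing notes and from the values. The MAS5 version was not given in the sources used here. The signal was linear and was not normalized again for the main results.

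The table held 22810 probe sets. Of these, 64 control probe sets were left out, which left 22746 for genes. A single gene was named for 13513 probe sets, several genes for 503, and 8730 were left unnamed here. Named probe sets were matched to the gene table by gene id (13436) or by locus (48), and 29 found no match there. They covered 13355 loci. Unnamed probe sets stayed in the tests and the counts, but no gene of theirs was named. The genes HSP101, HSFA2, APX2, HSP70B, HSP17.6II, MBF1C, HSP90.1, GOLS1, DREB2A, BIP3, HSFA1A and CCA1, chosen as a time course before the data were examined, had no named probe set and were not analysed here.

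Signals were transformed as log2(value + 10.7), where the added constant was the median over arrays of the 25th percentile. Fold changes are on this scale, which understates changes of genes with low signal. A probe set was kept where it lay above its array's 40th percentile on both arrays of at least 1 group, which kept 16782 and removed 5964. Of those kept, 9238 had 1 named gene.

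A linear model with 16 group means was fitted to all 32 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), with 16 residual degrees of freedom and a median prior of 8.24. There were 21 planned contrasts. P-values were adjusted by the Benjamini-Hochberg method within each contrast. A probe set passed where its adjusted p-value was below 0.05 and its log2 difference was at least 1 in size. Where a gene had several probe sets, each was tested. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures with matplotlib 3.10.9.

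No unheated plants were among the samples used, so the reference was the plants at 21 h of recovery. They were harvested at the clock hour at which the heat had begun, a day later. The other times were not matched to it by clock hour.

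Gene lists were tested with camera (limma) at a preset correlation of 0.01, with 1 probe set per locus (the highest mean), in 7 contrasts. Lists with fewer than 5 measured members were counted but not tested. Of 354 loci in 20 planned lists, 52 had a named probe set. The lists with measured members, their number given after each, were small heat shock proteins (9), HSP70 chaperones (2), HSP90, HSP100, HSP60 and co-chaperones (5), endoplasmic reticulum folding (4), reactive oxygen and heat-linked regulators (1), rapid stress response (3), abscisic acid and cold response (4), auxin response and growth (2), light harvesting (5), mitosis (3), DNA replication (1), circadian clock (1), cytosolic ribosomal proteins (3), phenylpropanoid synthesis (1), glucosinolate synthesis (1), root cell types (2) and commonly used reference genes (5). Heat shock factors, jasmonate and hypoxia genes had 0 named probe sets and were not analysed here.

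Because so few planned members could be named, 14 lists were added after the probe naming was known, and were adjusted as a family of their own. They were further co-chaperones (23), endoplasmic reticulum stress and degradation (16), nuclear-encoded photosynthesis (22), autophagy (9), cell division (23), glutathione transferases and glucosyltransferases (22), wall loosening (22), SWEET transporters (10), calmodulin-like and defence genes (18), cytosolic ribosomal proteins (41), RNA polymerases and rRNA processing (12), pentatricopeptide repeat proteins for organelle RNA (16), mitochondrion-encoded genes (15) and plastid-encoded genes (69). Added lists shared genes with planned lists, so their results are not independent. The list of HSP90, HSP100, HSP60 and co-chaperones, called the HSP90 list below, had the co-chaperones Hop1, Hop2, Hop3 and ROF2 among its 5 measured members. Hop3 and ROF2 were also among the added co-chaperones. All 5 light harvesting genes were among the 22 of nuclear-encoded photosynthesis. Counts over a list adjusted over the list alone equalled those adjusted over all probe sets in every list and contrast but 1, which is given with its result.

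Genes named in the results followed a rule set in advance. For 1 h of heat against 21 h of recovery and for 1 h of recovery against 3 h of heat, in each tissue, the candidates were the 10 largest increases and decreases. These had to pass, match 1 gene and have both arrays of one group beyond both of the other. For 3 h against 0.25 h of heat, the interactions and the tissue difference the number was 5 each way. From each list, up to 4 members with the largest difference could be named. Some were left out for length. Levels of listed genes at other times and in the other tissue, the HSP and photosynthesis genes followed through recovery, and the array measures were chosen after the values were seen.

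The alternatives planned were a smaller constant (0.25 times) and a larger one (4 times), no filter on low values, quantile normalization, scaling to the 75th percentile, eBayes without the trend, each tissue fitted alone, the replicate number as a block, each array left out, camera with an estimated correlation, and fry. Fry tests a list against no change, whereas camera tests it against the other genes. The 0.25 h heat samples as reference, and the contrast of 9 h with 3 h of recovery, were added after the values were seen.

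In a self-test on the comparison of 1 h of heat with 21 h of recovery in shoots, changes were planted among 16782 simulated probe sets, 50 of each size. Those recovered in the right direction were 50 at 1.5 log2, 49 at 2, 50 at 3 and 50 at 4. Of 16582 unchanged probe sets, 0 were called. A planted list of 10 members had a camera p-value of 1.03e-28, and 1 of 200 random lists had an unadjusted p-value below 0.05. Noise was drawn independently for each probe set. The self-test therefore does not show how often lists of correlated genes would pass without cause.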

Results

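Seedlings of the Col-0 accession of *Arabidopsis*, grown at 24 °C on Murashige and Skoog medium with 16 h days, were heated to 38 °C on day 16, 3 h into the light period. Shoots and roots were taken after 0.25, 0.5, 1 and 3 h of heat. They were also taken 1, 3, 9 and 21 h after the return from 3 h of heat to 25 °C. The comparisons asked which genes answered the heat, how far each answer had ended within 1 h of recovery, and whether shoots and roots differed. No unheated plants were among the samples used, so plants at 21 h of recovery served as the reference. The other times differ from it, and from each other, in clock hour as well as in heat. The labels do not say whether the 2 replicates were separate cultures, so the p-values measure only the spread between these arrays, which may be technical. Their number limits the precision.

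The median signal per array was 31.7 to 49.0, and log2 signals of replicate arrays correlated at 0.984 to 0.993. Signal from 25S ribosomal RNA in shoots was 104 ± 5.71 (mean ± SD) at 21 h of recovery, 1916 ± 180 at 1 h of heat and 2405 ± 7.74 at 3 h. In roots it was 456 ± 165, 2322 ± 152 and 3080 ± 431 at the same times. The actin 3′/5′ ratio in shoots was 5.39, 9.81 and 13.7 at these times, where the 1 h value is the mean of 14.9 on replicate 1 and 4.72 on replicate 2, so that its rise rests on 1 array. In roots it was 12.5, 20.4 and 19.4. The 100 highest probe sets held 13.9%, 14.8% and 14.9% of the signal in shoots and 8.57%, 10.9% and 11.8% in roots.

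After 1 h at 38 °C, shoots carried very high levels of transcripts for small heat shock proteins, which bind unfolding proteins. HSP17.6C was at 5479 ± 343 against a mean of 33.6 at 21 h of recovery (log2 difference 7.01 ± 0.31 SE, adjusted p = 2.11e-15), and HSP17.6B rose by 7.06 ± 0.36. Organelle members of the family rose as steeply, among them HSP23.5 (6.89 ± 0.25) and HSP26.5 (6.87 ± 0.27, 1835 ± 131 against 5.14 ± 3.25), with the endoplasmic reticulum member ATHSP22.0 at 6.51 ± 0.23. The peptidyl-prolyl isomerase ROF2, which binds HSP90, rose by 6.15 ± 0.22 to 5703 ± 301. Fes1A (5.52), Hop3 (5.61), which links HSP70 with HSP90, HSA32 (5.34) and HSC70-3 (4.07 ± 0.19, 3634 ± 358 against 207 ± 28.5) rose with it.

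Among the decreases in shoots, ATSPS4F, a sucrose-phosphate synthase, fell by 2.62 ± 0.14 (167 ± 11.6 against 1081 ± 25.4), and TBL26, of a family that acetylates wall polymers, fell by 2.99 ± 0.17. The deepest decrease was that of AT2G27420 (−4.42 ± 0.16, from 722 ± 46.5 at 21 h of recovery, adjusted p = 6.3e-17). AT1G06000 fell by 2.76 and AT3G44450 by 2.70, and both probe sets of AT5G54130 fell (−2.76 and −2.56). In all, 577 probe sets rose, 695 fell and the rest of 16782 did not pass. The balance turned after quantile normalization (589 rose, 502 fell) and with an added constant 4 times as large (391 and 284). The median over all genes was −0.08.

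Of 9 small heat shock protein genes 8 rose and 0 fell (median 6.51, camera adjusted p = 1.07e-16). Of 5 HSP90, HSP100, HSP60 and co-chaperone genes 3 rose, 0 fell and 2 did not pass (median 2.08, 1.06e-06), Hop2 by 2.08 while Hop1 was at 0.28. Both HSP70 chaperones rose, the other being Hsp70-2 (2.77). Among 23 added co-chaperones 15 rose and 0 fell (median 2.77, 3.65e-23), and among 16 genes of endoplasmic reticulum stress and degradation 4 rose and 0 fell (median 0.37, 4.19e-05), led by the derlin gene DER1 (3.07 ± 0.10) and BZIP28 (1.94), a membrane-bound regulator of the unfolded protein response. These calls held with an estimated correlation. Single members rose in the lists of endoplasmic reticulum folding (ATERDJ3B 1.10, 3 of 4 not passed), reactive oxygen and heat-linked regulators (HSA32, its only measured member), rapid stress (STZ 1.80, 2 of 3 not passed), abscisic acid and cold (COR47 1.10, 3 of 4 not passed) and auxin (IAA29 1.85, 1 of 2 not passed). After quantile normalization ATERDJ3B (0.98) and COR47 (1.00) lay just under the log2 threshold.

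Plastid-encoded transcripts also rose in shoots: 21 of 69 rose and 0 fell (median 0.77, camera adjusted p = 1.01e-17; adjusted p = 0.113 with an estimated correlation). The photosystem II gene psbD rose by 3.34 ± 0.38 (2718 ± 812 against 254 ± 25.0), ycf3 by 2.04 and psaC by 2.02. Of 15 mitochondrion-encoded genes 4 rose, among them nad4 (1.57) and nad5 (1.29), with a median of 0.32 (0.000738; adjusted p = 0.0972 with an estimated correlation). The 25S signal was higher in the same samples, as given above. Of 16 pentatricopeptide repeat genes, which process organelle RNA, 1 fell and 15 did not pass (median −0.70, 0.00626; adjusted p = 0.0972 with an estimated correlation). Cytosolic ribosomal genes had a median of 0.07 with 1 of 41 risen (0.0486; adjusted p = 0.774 with an estimated correlation, 0.376 after quantile normalization). Autophagy genes had a median of 0.16 with 1 of 9 risen, ATG8E, which was at 0.93 after quantile normalization (0.0246; adjusted p = 0.357 with an estimated correlation).

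Photosynthesis genes of the nucleus had hardly moved after 1 h. Of 5 light harvesting genes 0 rose and 0 fell (median 0.11, camera adjusted p = 0.848), with RCA, the Rubisco activase, at 0.21 and LHCB4.3 at −0.54. In the added list, which holds these 5 genes too, 1 of 22 rose (PORB; camera adjusted p = 0.457). The lists of cell division (1 of 23 fell, HTB2 −1.04 and −0.88 after quantile normalization, camera adjusted p = 0.329), glutathione transferases and glucosyltransferases (1 of 22 fell, 0.768), wall loosening (1 of 22 fell, EXLB1 −1.45, 0.768), SWEET transporters (1 of 10 fell, SWEET13 −1.88, 0.497), calmodulin-like and defence genes (2 of 18 rose, 0.497), RNA polymerases (0 of 12, 0.329) and reference genes (0 of 5, 0.887) did not pass. None of the measured genes of mitosis (3), DNA replication (1), the clock (1, GI at 0.52), planned ribosomal proteins (3), phenylpropanoids (1), glucosinolates (1) or root cell types (2) passed.

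Roots too had high levels of chaperone transcripts after 1 h of heat. HSP17.4-CIII rose by 6.12 ± 0.27 (3422 ± 276 against 38.8 ± 6.80, adjusted p = 4.79e-15), HSP17.6C by 6.02 (4133 ± 292 against 53.4 ± 7.68), HSP26.5 by 5.77 and the peroxisomal HSP15.7 by 5.46 ± 0.32. A gene with a DnaJ domain, AT1G71000, rose by 5.34, and HSC70-3 by 3.44 ± 0.19. STZ, a zinc-finger repressor of stress responses, rose by 2.71 ± 0.22 (860 ± 108 against 121 ± 3.45) and the dehydrin COR47 by 1.71 ± 0.12 (2924 ± 244 against 898 ± 196).

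Fewer probe sets fell than rose in roots. AT5G26270 fell by 2.99 ± 0.88 (a mean of 75.4 against 681 ± 174, adjusted p = 0.00875, but 0.0538 without replicate 1 of roots at 1 h of heat), AT1G04770 by 1.99 ± 0.17, AT5G18840 by 1.96 and AT2G22590 by 1.88. The histone gene HTB2 fell by 1.21. In all, 603 probe sets rose and 377 fell. The median over all genes was −0.14, and differences in roots are to be read relative to it. Of 5 reference genes 0 passed.

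In roots 8 of 9 small heat shock protein genes rose (median 5.57, camera adjusted p = 1.19e-18), 3 of 5 in the HSP90 list (median 1.55, 1.81e-05), 15 of 23 added co-chaperones (median 2.01, 1.44e-21) and 4 of 16 genes of endoplasmic reticulum stress, among them DER1 at 1.97 and BZIP28 at 1.38 (median 0.22, 0.000312). All 4 held with an estimated correlation, and both HSP70 chaperones rose. Plastid-encoded genes rose in 14 of 69 cases, among them accD (1.77) and psaI (1.63) (median 0.57, 4.82e-17; adjusted p = 0.123 with an estimated correlation). Of 15 mitochondrion-encoded genes 2 rose, nad4 and nad5 (median 0.39, 7.78e-05; adjusted p = 0.0502 with an estimated correlation). The 25S signal and the actin ratio were higher in these root samples too. Calmodulin-like and defence genes, many of which bind calcium, moved both ways: 5 of 18 rose, CML23 by 2.34 and CML37 by 1.84, and 1 fell (median 0.14, 0.0143; adjusted p = 0.123 with an estimated correlation). Light harvesting genes did not pass as a list (0.0736), although RCA rose by 1.70 ± 0.13 and LHCB4.2 by 1.09 (0.63 without replicate 2 of roots at 21 h of recovery). The lists of autophagy (0 of 9, 0.679), cell division (1 of 23 fell, 0.226), glutathione transferases (1 of 22 fell, 0.825), wall loosening (3 of 22 fell, EXLB1 by 1.31 and EXPB2 by 1.22, 0.794), SWEET transporters (0 of 10, 0.825), ribosomal proteins (1 of 41 fell, 0.0878), RNA polymerases (0.415), pentatricopeptide repeat genes (0.42) and nuclear photosynthesis (2 of 22 rose, 0.528) did not pass. The ribosomal list passed in opposite directions under other scalings. Its median was −0.30 after quantile normalization (camera adjusted p = 1.4e-05) and 0.14 with 75th percentile scaling (camera adjusted p = 0.0111).

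The answer grew over the 3 h of heat. At 0.25 h the small heat shock protein genes were still low: 0 rose and 3 of 9 fell against 21 h of recovery in each tissue (medians −0.38 in shoots and −0.53 in roots; camera adjusted p = 0.000848 and 0.0179, and adjusted p = 0.244 and 0.456 with an estimated correlation). In shoots HSP15.7 was at 25.1 and 22.7 at 0.25 h and at 132 and 81.9 at 21 h, while HSP23.5 was at 22.1 and 20.0, and at 22.5 and 17.5. Without unheated plants, early decreases could not be told from a 21 h level that was still raised. Where it was still raised, rises against it are understated. In roots at that time 5 calmodulin-like and defence genes had risen (median 0.42, 3.96e-07). At 0.5 h, 4 small heat shock protein genes had risen in shoots and 3 in roots (camera adjusted p = 0.000226 and 0.000392, and adjusted p = 0.189 and 0.234 with an estimated correlation), with 9 and 8 co-chaperones. By 3 h, 9 of 9 had risen in shoots (median 6.79) and 8 in roots (6.15).

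Counts of passing probe sets against 21 h of recovery followed the same course. In shoots 95 rose and 39 fell at 0.25 h, 210 and 96 at 0.5 h, and 1196 and 1535 at 3 h. In roots 125 rose and 20 fell at 0.25 h, 237 and 33 at 0.5 h, and 1135 and 1715 at 3 h. With a constant 4 times as large the balance at 3 h turned, to 765 rises and 751 decreases in shoots and 789 and 749 in roots. The median over all genes at 3 h was −0.09 in shoots and −0.15 in roots.

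**Figure D1:**
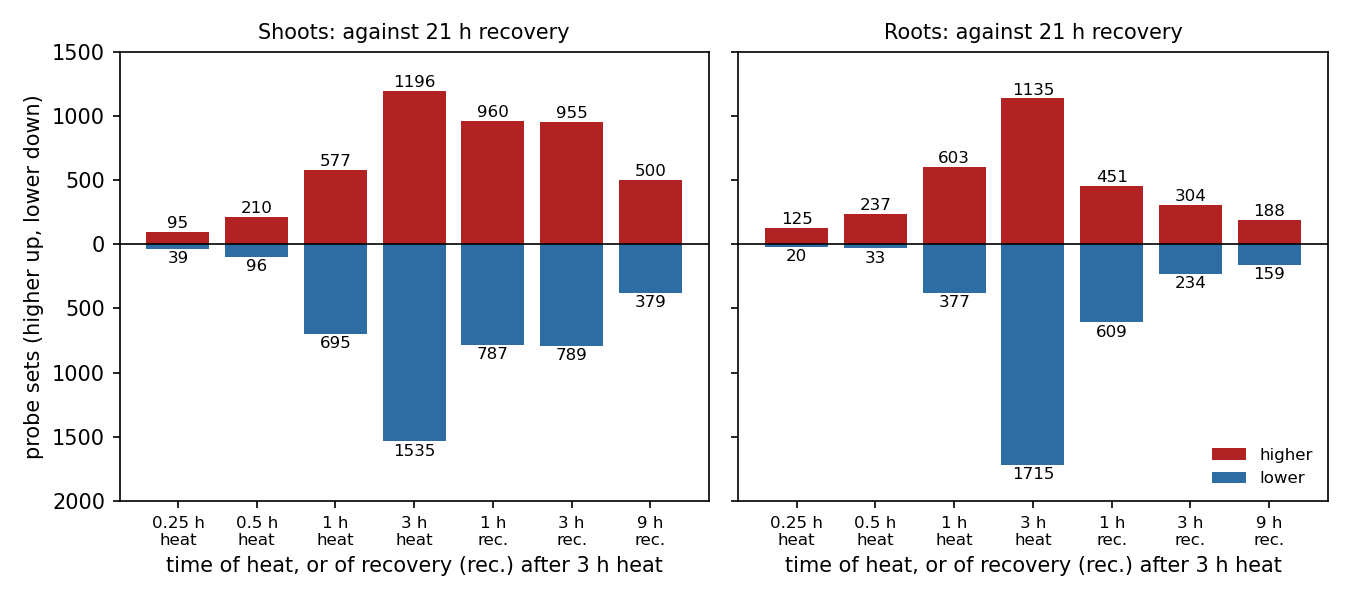
Numbers of probe sets that rose or fell against 21 h of recovery (vertical axis) at the 7 other times (horizontal axis), in shoots and roots. The counts were largest at 3 h of heat, with 1196 risen and 1535 fallen in shoots and 1135 and 1715 in roots.

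**Figure D2:**
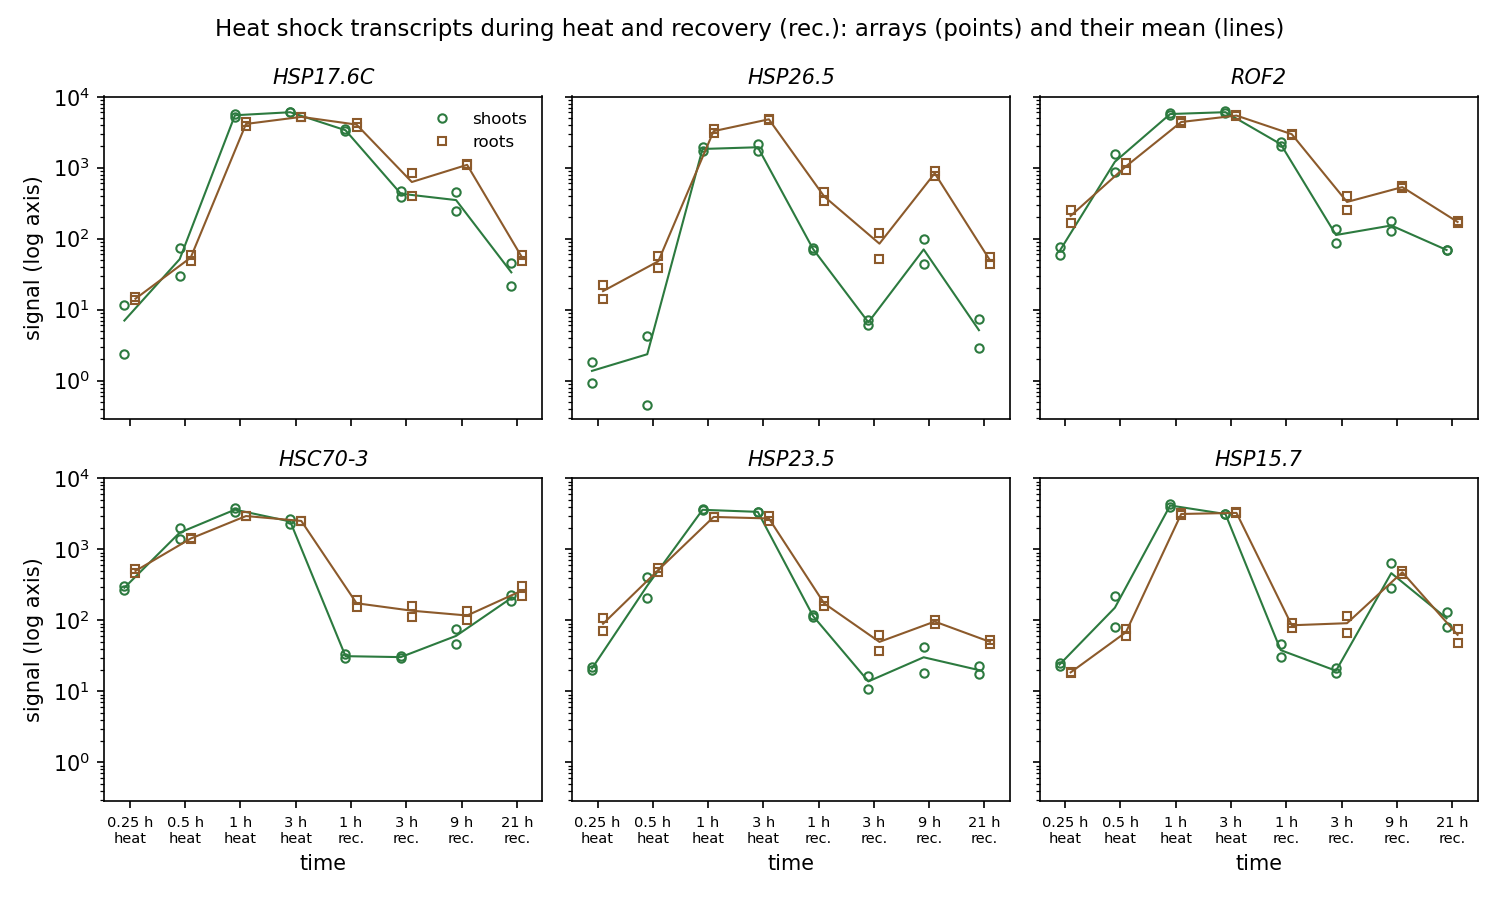
Signal of HSP17.6C, HSP26.5, ROF2, HSC70-3, HSP23.5 and HSP15.7 (logarithmic vertical axis) at the 8 times, with single arrays as points and lines through the group means, for shoots and roots. HSC70-3 in shoots was at 2477 at 3 h of heat and at 31.4 after 1 h of recovery.

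Between 0.25 and 3 h of heat, shoots gained chaperone transcripts. HSP17.6B went from a mean of 4.80 to 5714 ± 64.6 (log2 difference 8.54 ± 0.36), HSP17.6C rose by 8.46 and ATHSP22.0 by 7.63, with Hop3 (6.56), HSA32 (6.37) and ROF2 (6.30) close behind. ATSPS4F fell by 3.88 ± 0.14, from 695 ± 12.5 to 37.1 ± 0.795, and AT1G13650 by 3.91. Histone genes HTB2 (−1.95) and HTB11 (−1.55) and the spindle checkpoint gene BUB3.1 (−1.43) fell, as did DFR (−1.59) of flavonoid synthesis. The ubiquitin-like autophagy gene APG8A rose by 1.83 and the clock gene GI by 1.49. These 2 times also differ in clock hour, so for GI heat and time of day could not be told apart.

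In this comparison 1015 probe sets rose and 1384 fell in shoots, against a median over all genes of −0.11, but 664 rose and 589 fell with a constant 4 times as large. Small heat shock proteins (8 of 9 rose, median 6.74, camera adjusted p = 4.01e-13), the HSP90 list (3 of 5, 2.17, 1.89e-06), co-chaperones (16 of 23, 2.98, 1.02e-18) and endoplasmic reticulum stress (5 of 16, 0.66, 2.32e-05) held with an estimated correlation. So did mitochondrion-encoded genes, of which 13 of 15 rose (median 2.41, 1.22e-15): nad5 by 4.54 ± 0.13 (686 ± 1.41 against 19.3 ± 0.662), nad6 by 4.05 and matR by 3.68. Cell division genes fell in 7 of 23 cases (median −0.78, 2.98e-05; adjusted p = 0.164 with an estimated correlation), and 1 of 9 autophagy genes rose (median 0.63, 0.00145; adjusted p = 0.164 with an estimated correlation). Plastid-encoded genes had a median of 0.24, with 9 risen and 2 fallen (0.00705; adjusted p = 0.811 with an estimated correlation and 0.453 after quantile normalization). The 25S signal and the actin ratio were higher at 3 h in the same samples.

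Roots over the same interval gained chaperone transcripts too, and several wall genes fell. In shoots 2 of 22 wall genes fell (EXPB1 −1.28) and 1 rose (XTH16 1.19), and the list did not pass (camera adjusted p = 0.823). In roots the expansin EXPA4 fell by 2.68 ± 0.20 (53.4 ± 0.808 against 401 ± 50.0), EXPB3 by 2.04 and the xyloglucan enzyme XTH20 by 1.55. AT4G24780 fell by 3.16 ± 0.17, and the glutathione transferases GSTU20 (−2.27), GSTU25 (−2.21) and GSTU26 (−2.18), which conjugate toxic compounds, fell too. HSP17.6C rose by 7.70, ATHSP22.0 by 7.50 and AT1G71000 by 6.99. RCA rose by 2.55 ± 0.13 and LHCB4.2 by 1.52, both photosynthesis genes, while BCAT4 of glucosinolate synthesis fell by 1.89.

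In roots 1016 probe sets rose and 1539 fell, against a median over all genes of −0.16, but 706 rose and 652 fell with a constant 4 times as large. Small heat shock proteins (8 of 9, median 6.81, camera adjusted p = 1.13e-12), the HSP90 list (3 of 5, 1.98, 0.00184), co-chaperones (15 of 23, 2.32, 2.27e-13) and mitochondrion-encoded genes (14 of 15, 2.92, 3.66e-18; cox2 by 4.64 ± 0.18, from a mean of 10.6 to 527 ± 123) held with an estimated correlation. In these root samples the 25S signal went from 722 ± 220.4 to 3080 ± 431 and the actin 3′/5′ ratio rose to 19.4. The following did not: endoplasmic reticulum stress (5 of 16 rose, 0.00591; adjusted p = 0.0741 with an estimated correlation), light harvesting (2 of 5 rose, 0.0299; adjusted p = 0.218 with an estimated correlation), plastid-encoded genes (7 of 69 rose, 0.000183; adjusted p = 0.487 with an estimated correlation). Autophagy (1 of 9 rose, 0.00109; adjusted p = 0.177 with an estimated correlation) and cell division (7 of 23 fell, among them BUB3.1, −1.76, 0.00124; adjusted p = 0.318 with an estimated correlation) did not hold either. Of 22 wall genes 7 fell and 1 rose, and of 22 glutathione transferase and glucosyltransferase genes 5 fell, but neither list passed (0.116 and 0.179).

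Within 1 h of the return to 25 °C many chaperone transcripts had fallen steeply in shoots. HSP15.7 went from 3152 ± 9.32 at 3 h of heat to 38.1 ± 11.2 (−6.04 ± 0.32, adjusted p = 1.11e-13), and HSC70-3 from 2477 ± 323 to 31.4 ± 3.05 (−5.88 ± 0.19, adjusted p = 1.82e-17). HSP23.5 fell by 4.75 and the Hikeshi-like AT1G66080 by 5.14, while ROF2 (−1.49), HSA32 (−1.59) and Hop3 (−1.92) fell far less. HSP17.6C was still at 3265 and 3477, against 6031 and 6056 at 3 h of heat. DER1 fell by 2.87 and BZIP28 by 2.61. Among the increases, AT1G13650 rose by 2.97 ± 0.23 to 225 ± 12.5, the beta-glucosidase BGLU44 by 2.42 ± 0.13 and CCT2, of phosphatidylcholine synthesis, by 2.26.

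Here 1179 probe sets rose and 770 fell in shoots, a share of rises of 60.5% that was 45.0% after quantile normalization, and 355 rose and 508 fell with a constant 4 times as large. The median over all genes was 0.14, and differences are to be read relative to it. The HSP90 list (3 of 5 fell, median −1.49, camera adjusted p = 0.000517), co-chaperones (14 of 23 fell and 2 rose, −1.92, 4.87e-12), endoplasmic reticulum stress (5 of 16 fell, 9.12e-06) and mitochondrion-encoded genes (8 of 15 fell, −1.07, 2.23e-09) held with an estimated correlation. So did 2 lists that turned upward, RNA polymerases and rRNA processing (3 of 12 rose, median 0.72, 0.00028; NRPA2 of RNA polymerase I by 1.67) and pentatricopeptide repeat genes (4 of 16 rose, 0.82, 0.000917; PPR596 by 2.12). Small heat shock proteins fell in 5 of 9 cases (−2.83, 4.64e-07; adjusted p = 0.0653 with an estimated correlation), and plastid-encoded genes fell in 16 of 69, psbD by 2.80 (−0.49, 1.41e-09; adjusted p = 0.253 with an estimated correlation). Cell division genes rose in 3 of 23 cases (0.47, 0.0244; adjusted p = 0.403 with an estimated correlation) and 2 of 22 wall genes fell (0.0207; adjusted p = 0.149 with an estimated correlation). The 25S signal fell to 203 ± 65.8 in these shoots. Both HSP70 chaperones fell, and in the cold list COR15B rose by 1.71 and COR47 fell by 1.11 (−0.84 after quantile normalization).

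Recovery in roots also lowered many chaperone transcripts within 1 h. HSP15.7 fell by 5.10 ± 0.32 (85.4 ± 10.6 against 3272 ± 89.3), AT1G71000 by 4.47, HSP23.5 by 3.89 and HSC70-3 by 3.78 ± 0.19 (175 ± 28.6 against 2522 ± 22.6). HSP17.6C stayed high, at 3793 and 4297 against 5259 and 5138 at 3 h of heat. The glucosyltransferase gene UGT85A2 rose by 2.73 ± 0.20, AT1G06000 by 2.66 and GAT1_2.1 by 2.22, and the glutathione transferase gene GSTU27 rose by 1.84. RCA (−2.10) and LHCB4.2 (−1.26) fell again, as did the stress genes STZ (−1.67) and COR47 (−1.33, and −0.70 after quantile normalization).

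In roots 819 probe sets rose and 705 fell, a share of rises of 53.7% that was 40.9% after quantile normalization, against a median over all genes of 0.15. With a constant 4 times as large 275 rose and 468 fell. Co-chaperones (14 of 23 fell, median −1.45, camera adjusted p = 1.17e-11), endoplasmic reticulum stress (4 of 16 fell, 0.000418) and mitochondrion-encoded genes (3 of 15 fell, −0.62, 1e-05) held with an estimated correlation. In the same root samples the 25S signal fell from 3080 to 840.0 and the actin 3′/5′ ratio from 19.4 to 10.03. Small heat shock proteins fell in 5 of 9 cases (−1.22, 1.87e-05; adjusted p = 0.121 with an estimated correlation), the HSP90 list in 2 of 5 (−0.87, 0.00446; adjusted p = 0.0751 with an estimated correlation and 0.0591 after quantile normalization) and plastid-encoded genes in 5 of 69 (−0.27, 1.8e-06; adjusted p = 0.49 with an estimated correlation). Ribosomal genes had a median of −0.25 (1 of 41 fell, 1e-05; adjusted p = 0.375 with an estimated correlation), which became 0.13 after quantile normalization (adjusted p = 0.26). RNA polymerases and pentatricopeptide repeat genes did not pass (0.37 and 0.652).

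**Figure D3:**
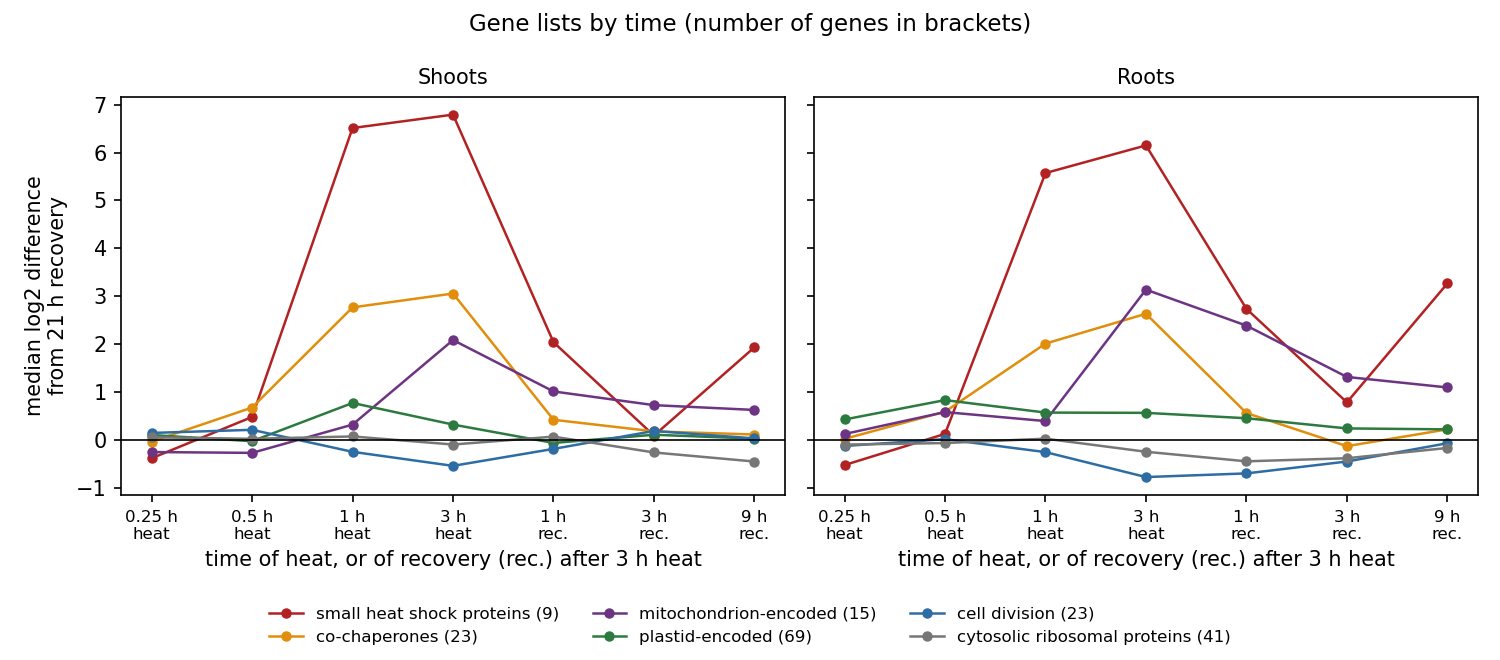
Median log2 difference from 21 h of recovery (vertical axis) of 6 gene lists at the 7 other times (horizontal axis), with a panel for each tissue. Mitochondrion-encoded genes reached 2.08 in shoots and 3.14 in roots at 3 h of heat.

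Later in recovery more probe sets differed from 21 h in shoots than in roots. These times also differ from 21 h in clock hour, so unfinished recovery and time of day could not be told apart. At 1, 3 and 9 h of recovery 960, 955 and 500 probe sets were raised in shoots against 21 h and 787, 789 and 379 were lowered, a balance that was even at 1 h (792 and 794) and turned at 3 h (792 and 816) after quantile normalization. In roots 451, 304 and 188 were raised and 609, 234 and 159 lowered. At 9 h, 6 of 9 small heat shock protein genes were raised in shoots (median 1.93, camera adjusted p = 6.51e-07; adjusted p = 0.138 with an estimated correlation) and 7 in roots (3.27, 9.49e-18), where the call held. In roots at that time 9 of 15 mitochondrion-encoded genes were also raised (median 1.09, 1.22e-22), and in shoots ribosomal genes had a median of −0.45 with 0 of 41 past the thresholds (2.45e-15; adjusted p = 0.2 with an estimated correlation).

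Shoots and roots answered with many of the same genes. After 1 h of heat 331 probe sets rose in both tissues (20.7 by chance), 86 fell in both (15.6 by chance) and 4 moved in opposite directions. After 3 h the numbers were 623 (80.9), 542 (157) and 12, and in the 1 h of recovery 242 (57.5), 386 (32.3) and 3. Across all genes the differences of the tissues correlated at 0.684 after 1 h of heat, 0.659 after 3 h and 0.632 in recovery, although genes are not independent replicates.

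The size of the answer differed by tissue for some genes, and for several of the chaperones that difference depended on the normalization. At 1 h, relative to 21 h of recovery, shoots exceeded roots for ROF2 (1.56), Hop3 (1.65), BOB1 (1.85), HSP23.5 (1.32 ± 0.35, adjusted p = 0.0104) and DER1 (1.10), and for IAA29 (1.79), an auxin response repressor. Roots exceeded shoots for HSP17.4-CIII (−1.17, adjusted p = 0.0379), RCA (−1.49), the calcium-binding CML37 (−1.89) and CML23 (−1.14), the ubiquitin ligase PUB19 (−1.70) and the dehydrin LTI30 (−1.01). For ROF2 and HSP23.5 the difference came in part from a lower 21 h level in shoots. ROF2 was at 69.2 and 69.5 in shoots at 21 h against 180 and 164 in roots. At 1 h it was at 5915 and 5490 against 4523 and 4285. HSP23.5 had 21 h means of 20.0 in shoots and 49.9 in roots. After quantile normalization the differences of ROF2 (0.81), Hop3 (0.77), HSP23.5 (0.34) and DER1 (0.68) did not pass, nor did that of LTI30 (−0.82), while BOB1 stayed past the thresholds. CML23 (−0.89) did not pass with a constant 0.25 times as large. That of HSP17.4-CIII did not pass when any of several single arrays was left out (adjusted p = 0.0666 without replicate 1 of shoots at 1 h of heat). This interaction passed for 896 probe sets at 1 h, 373 higher in shoots and 523 lower, and for 2192 at 3 h, 1155 and 1037 (1034 and 1148 after quantile normalization).

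Among small heat shock proteins the interaction at 1 h was higher in 3 of 9 genes (4 adjusted over the list alone) and lower in 1 (median 0.99, camera adjusted p = 0.284). HSP26.5 (1.10) was counted as higher, although its signal at 1 h was larger in roots (3480 and 3064) than in shoots (1743 and 1927). Its 21 h means were 5.14 in shoots and 49.5 in roots. The HSP90 list (2 of 5 higher, median 0.53, 0.0148; adjusted p = 0.0981 with an estimated correlation and 0.0794 after quantile normalization) and co-chaperones (3 of 23 higher, 0.50, 0.00514; adjusted p = 0.356 with an estimated correlation and 0.281 after quantile normalization) passed only at the preset correlation. Hop3 and ROF2 were counted as higher in both of these lists. Among calmodulin-like and defence genes 4 of 18 were lower, but the list did not pass (0.0647). At 3 h the HSP90 list was higher in 3 of 5 genes (1.34, 0.0192; adjusted p = 0.106 with an estimated correlation). Light harvesting genes were lower in 3 of 5 (−1.30, 0.00434; adjusted p = 0.106 with an estimated correlation), mitochondrion-encoded genes in 5 of 15 (−0.87, 0.00218; adjusted p = 0.196 with an estimated correlation) and plastid-encoded genes in 11 of 69 (−0.39, 0.00122; adjusted p = 0.608 with an estimated correlation), while 8 of 22 glutathione transferase and glucosyltransferase genes were higher (0.25, 0.0358; adjusted p = 0.259 with an estimated correlation).

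Over all 8 times photosynthesis genes were among the largest differences between shoots and roots. PRK, the phosphoribulokinase of the Calvin cycle, was higher in shoots by 6.94 ± 0.07, PSAE-1 of photosystem I by 6.57, SBPASE by 6.40, ECS1 by 7.31 ± 0.05 and the sucrose exporter SWEET11 by 5.23. Higher in roots were the osmotin-like OSM34 (−6.85 ± 0.11), AT4G15390 (−6.72), the dehydrin LTI30 (−5.26), UGT76B1 (−5.03) and GSTU22 (−4.32). In all 2455 probe sets were higher in shoots and 3078 in roots, with a median over all genes of −0.29 (1846 and 1710 with a constant 4 times as large).

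All 22 nuclear photosynthesis genes were higher in shoots (median 5.05, camera adjusted p = 4.38e-16; adjusted p = 0.0626 with an estimated correlation), as were 5 of 5 light harvesting genes (5.06, 7.24e-05; adjusted p = 0.0578 with an estimated correlation) and 64 of 69 plastid-encoded genes (2.48, 3.39e-25; adjusted p = 0.0743 with an estimated correlation). The 5 light harvesting genes are all among the 22, so they are not a separate result. Pentatricopeptide repeat genes were higher in 8 of 16 cases and lower in 1 (0.96, 0.000802; adjusted p = 0.0626 with an estimated correlation), and SWEET transporters were higher in 3 of 10 (0.00854; adjusted p = 0.177 with an estimated correlation). Calmodulin-like and defence genes were lower in 11 of 18 cases, WRKY6 by 2.92 (−1.26, 0.023; adjusted p = 0.149 with an estimated correlation). Small heat shock proteins as a list did not pass (2 of 9 higher, 1 lower, −0.09, 0.513). Photosynthesis genes were far lower on root arrays: PSAE-1 at 43.6 ± 14.8 against 5015 ± 543 in shoots, LHCB4.1 at 187 against 5345, LHCB4.2 at 79.6 against 4561, RCA at 171 against 4473 and LHCB4.3, near background in roots, at 23.4 against 575. The root hair expansins EXPA7 and EXPA18 were at 12.4 and 19.7 in shoots against 45.5 and 42.9 in roots.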

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

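The interaction counts and genes came from planned tests, while the mitochondrion-encoded and co-chaperone lists were added once the probe naming was known. The cases weighed, with the explanations and their tests, were chosen only after the results were seen.

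The interaction of tissue and heat stood out for its size, with 896 probe sets past the thresholds at 1 h of heat against 21 h of recovery and 2192 at 3 h. At 1 h the largest interactions higher in shoots were psbD 3.21 (shoots 3.34, roots 0.13), AT4G15680 2.81 (3.16, 0.35), AT4G15660 2.76 (2.72, −0.04), AT5G47610 2.67 (3.12, 0.44) and AT2G20670 2.50 (0.59 in roots). The largest lower in shoots were AT2G27420 −4.38 (−4.42, −0.04), TBL26 −2.93 (−2.99, −0.06), AT5G42760 −2.78 (−2.15, 0.63), AT5G08240 −2.55 (−0.53, 2.02) and AT5G66740 −2.41 (−2.31, 0.10). AT4G15680 and AT4G15660 are paralogs of very similar sequence, whose probe sets may share signal.

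At 3 h the largest higher in shoots were AT5G57785 3.27 (shoots 0.34, roots −2.93), AT3G28510 3.19 (−0.05, −3.23), AT4G15680 3.18 (3.42, 0.24), AT2G15960 3.17 (−0.06 in roots) and AT4G19430 3.16 (3.67, 0.51). The largest lower were AT2G27420 −5.00 (−5.03, −0.03), ATSPS4F −4.01 (−4.51, −0.51), AT1G13650 −3.98 (−3.81, 0.18), TBL26 −3.67 (−3.68, −0.02) and AT1G55960 −3.61 (−2.90, 0.71). At 1 h the HSP90 list and the co-chaperones stood out with medians of 0.53 and 0.50, but neither call held with an estimated correlation (adjusted p = 0.0981 and 0.356) or after quantile normalization (0.0794 and 0.281).

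Most of the genes named here lay near background in a tissue, where a decrease could not be seen but a large rise could. In roots AT4G15680, AT4G15660, AT5G47610, AT2G27420, TBL26, AT5G42760, AT5G66740, AT2G15960, AT4G19430, ATSPS4F and AT1G13650 lay below the 40th percentile at both times compared, as did AT5G08240 and AT3G28510 in shoots. For AT2G27420, TBL26, AT5G42760, AT5G66740, ATSPS4F, AT1G13650 and AT3G28510 the other tissue showed a decrease, so a like decrease there could not have shown. At 1 h 189 of the 373 interactions higher in shoots (50.7%) and 227 of the 523 lower (43.4%) belonged to probe sets below that percentile at both times in at least 1 tissue. At 3 h the numbers were 426 of 1155 (36.9%) and 361 of 1037 (34.8%). Over all 16782 probe sets they were 4359 at 1 h and 3999 (23.8%) at 3 h.

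Mitochondrion-encoded transcripts rose between 0.25 and 3 h of heat, with list medians of 2.41 in shoots and 2.92 in roots. The authors' scaling was tested first: under 2 other scalings the lowest median was still 2.29, so the rise did not depend on the choice among these scalings. Each of them brings the arrays to a like bulk signal. None could therefore show a change in the total amount of mRNA relative to organelle RNA. More labelled RNA without a poly(A) tail was tested against plastid-encoded genes, whose medians were 0.24 and 0.38, and the lower quartile for mitochondria stayed 0.954 above the upper quartile for plastids. That gap cannot decide the question, because plastid-encoded genes did not follow 25S. In shoots their median against 21 h of recovery fell from 0.77 at 1 h to 0.32 at 3 h, while 25S rose from 1916 to 2405. As 25S signal and the actin ratio rose in the same samples, a part of the mitochondrial rise could come from such labelling. In both tissues, though, 25S was already high at 1 h, when the mitochondrial median against 21 h of recovery was still low. That median was 0.32 in shoots and 0.39 in roots, with 25S at 1916 and 2322. At 3 h the medians were 2.08 and 3.14, with 25S at 2405 and 3080. These values argue against labelling of the kind that 25S tracks as the whole cause.

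As a further case, in roots the photosynthesis gene RCA was at 592 ± 34.3 at 3 h of heat against 73.7 ± 13.6 at 21 h of recovery (2.85) and LHCB4.2 was higher by 2.13, while PSAE-1 was at −0.26. Below the log2 threshold, PORB was at 0.72 (adjusted p = 0.000736), LHCB4.1 at 0.64 (0.000315), CHLM at 0.57 (0.00051) and PSB27 at 0.54 (0.00207). RNA of shoots in the root samples would have needed a share of 9.75% for RCA and 3.29% for LHCB4.2. Of 20 other photosynthesis probe sets 13 (65%) lay below the lower share on both root arrays, which argues against mixing as the cause for both genes. Cross-hybridisation was not tested and stays a possible explanation.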

How the results depend on the processing

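Settings were planned, apart from the 0.25 h reference and the 9 h to 3 h recovery contrast, chosen after the results were seen. The added lists were chosen once the probe naming was known. A gene or list was followed once per comparison, which gave 434 gene results and 126 list results from 18 tested lists. The gene results followed had all passed the thresholds in the main fit, so a turn to the opposite direction was unlikely from the start, and none was seen. A constant 4 times as large ended the call of 85 gene results, quantile normalization of 44, leaving out some single array of 43 and 75th percentile scaling of 17. An estimated correlation ended 26 list calls, leaving out some array 5 and quantile normalization 6, while fry gained 29, quantile normalization 11, leaving out some array 10 and no filter 5. The median of the ribosomal list changed sign after quantile normalization at 1 h of heat in shoots (from 0.07 to −0.0533, with −0.00841 without shoots, 1 h heat replicate 2 and 0.15 without replicate 1) and in 1 h of recovery in roots (from −0.25 to 0.13), in each case with the call lost. Quantile normalization also made the ribosomal list pass where it had not. These were 1 h of heat in roots (median −0.303), 3 h against 0.25 h of heat in shoots (−0.257) and roots (−0.460), 1 h of recovery against 3 h of heat in shoots (0.440) and the interaction at 1 h (0.253). With 75th percentile scaling it passed at 1 h of heat in roots in the other direction (0.141). The 0.25 h reference moved no count by more than 1.5 times.

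With a constant 4 times as large, counts of passing probe sets in shoots at 0.25, 0.5, 1 and 3 h of heat and 1, 3 and 9 h of recovery were 56, 148, 675, 1516, 953, 1031 and 520 (from 134, 306, 1272, 2731, 1747, 1744 and 879). In roots they were 57, 125, 495, 1538, 553, 240 and 183 (from 145, 270, 980, 2850, 1060, 538 and 347). For 3 h against 0.25 h of heat they were 1253 and 1358 (from 2399 and 2555), for 1 h of recovery against 3 h of heat 863 and 743 (from 1949 and 1524), and for 9 h against 3 h of recovery 490 and 255 (from 939 and 583). The interactions gave 392 and 1100 (from 896 and 2192) and the tissue difference 3556 (from 5533). With that constant rises outnumbered decreases in shoots at 1 h of heat (391, 284), at 3 h in both tissues (765, 751 and 789, 749), for 3 h against 0.25 h (664, 589 and 706, 652) and for the tissues (1846, 1710), where decreases had been more. For 1 h of recovery against 3 h of heat (355, 508 and 275, 468) and the interaction at 3 h (505, 595) decreases became more. A constant 0.25 times as large gave 217 and 513 in shoots at 0.25 and 0.5 h.

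Planned lists that passed for 1 h of recovery against 3 h of heat in roots were 2, but 1 after quantile normalization and 0 with an estimated correlation. With fry, which tests against no change and not against other genes, 4 passed. In shoots they were 2, but 1 with an estimated correlation. For the interaction at 1 h the 1 list became 0 with an estimated correlation and 2 without roots, 3 h heat + 21 h recovery replicate 1.

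Scaling moved the share of rises in 1 h of recovery against 3 h of heat from 60.5% (1179 rose, 770 fell) to 45.0% (694, 847) by quantile normalization and 44.8% (802, 988) by the 75th percentile in shoots, and from 53.7% (819, 705) to 40.9% (590, 851) and 36.1% (517, 915) in roots. The 75th percentile also moved it at 1 h of heat from 45.4% (577, 695) to 56.7% (700, 534) in shoots and from 61.5% (603, 377) to 73.8% (703, 250) in roots, at 3 h in roots from 39.8% (1135, 1715) to 50.4% (1344, 1324), and for 3 h against 0.25 h of heat in roots from 39.8% (1016, 1539) to 49.8% (1185, 1193). Smaller shifts by quantile normalization turned the balance at 1 h of heat in shoots (589, 502), at 3 h of recovery in shoots (792, 816) and for the interaction at 3 h (1034, 1148). At 1 h of recovery in shoots it became even (792, 794). The 75th percentile turned it in shoots at 1 h (815, 913) and 3 h of recovery (812, 934), for the interaction at 3 h (1040, 1155) and for the tissues (2638, 2619).

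Replicates share only a number. With that number as a replicate block the interaction count at 1 h was 894 instead of 896, and no count moved by more than 1.5 times. The block ended the call of HSP26.5 in that interaction (adjusted p = 0.0541) and of the ribosomal list at 1 h of heat in shoots (0.0533), and no other call followed. Differences between replicates 1 and 2 correlated at −0.193 to 0.161 over 120 pairs of groups, with a median of 0.00399.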

Other observations

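The contrast of 9 h with 3 h of recovery, the tests of mixing and the random splits were chosen only after the results were seen.

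Some small heat shock protein genes rose again late in recovery. Between 3 and 9 h of recovery HSP15.7 rose in shoots by 3.86 (19.5 ± 2.18 to 464 ± 252), HSP26.5 by 2.14 and HSP18.5 by 2.09, and in roots HSP26.5 rose by 3.23 (85.1 ± 47.1 to 834 ± 109) and HSP18.5 by 1.82. Others went on falling in shoots, HSP17.6B by 1.24 and ATHSP22.0 by 1.51. In roots HSP15.4 fell by 1.24, from 52.7 ± 1.36 to 16.1 ± 0.538, after a mean of 20.5 at 3 h of heat. Of the 9 genes 4 rose and 2 fell in shoots (camera adjusted p = 0.0372; adjusted p = 0.674 with an estimated correlation), and 3 rose and 1 fell in roots (0.0183; adjusted p = 0.364 with an estimated correlation). In this contrast 510 probe sets rose and 429 fell in shoots, and 215 and 368 in roots.

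This late rise did not depend on the choice among the scalings used, as all 7 increases over both tissues stayed under both other scalings. RNA of plants at 3 h of heat mixed into the 9 h samples would have needed shares of at least 3.29% in shoots and 7.37% in roots. Of other strongly heat-raised probe sets 18 of 52 (34.6%) in shoots and 14 of 54 (25.9%) in roots lay below those shares, which argues against mixing, although the bound was set with the values known and the root value lies close to it. Clock time and recovery time were not separable here, and either could explain the rise.

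The tissue difference was larger than any drawn at random. Of 100 splits of the arrays, the real one included, 1 had 5533 or more passing probe sets, and the highest other had 3158. As so many genes differed strongly between the tissues, this outcome was all but fixed beforehand and adds no support.

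The GAPDH 3′/5′ ratio was 1.16 to 2.26 and the actin ratio 3.68 to 21.9 over all arrays. The 2 shoot arrays at 9 h of recovery differed widely in 25S signal, 1270.3 on replicate 1 and 88.6 on replicate 2. The array with more 25S also had more signal of HSP15.7 (642 against 285) and HSP26.5 (97.5 against 43.6), while both arrays at 3 h of recovery were lower for HSP15.7 (a mean of 19.5) and HSP26.5 (7.24 and 6.04). Those arrays at 3 h of recovery had 25S at 1308 and 1270, so high 25S did not go with high signal of these genes there.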
